A study of Rattus norvegicus with 23 samples.

How the data were processed

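The deposited table holds integer read counts per gene for 23 libraries of rat liver, in 28913 rows, and its values are counts per the submitters' processing notes. By those notes the authors checked reads with FastQC, trimmed them with Trim Galore, aligned them with STAR 2.7.9a and counted them with featureCounts of Subread 2.0.3. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes are uncertain. Libraries were made with a stranded mRNA kit, and the labels placed 6 in Control, 7 in LPS and 10 in Selfox. Even numbers made up 66.1% to 74.9% of the counts from 1 to 9 in each library and 51.0% to 53.7% of those from 100 to 999, so part of the low counts may include both ends of a read pair; a run with all counts divided by 2 is among the alternatives.

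Genes were kept by filterByExpr of edgeR with its default minimum count of 10, which left 15079 of the 21753 genes with any count, holding 99.99% of the counts. Counts were scaled by TMM factors, and all 3 groups were fitted together with robust quasi-likelihood dispersion (biological coefficient of variation 0.235). The 3 comparisons, LPS with Control, Selfox with Control and Selfox with LPS, were tested by edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. CPM values were computed from TMM-scaled library sizes, and log2 CPM used a prior count of 2. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

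Gene lists of pathways, complexes and cell type markers, 41 in all, were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. Of 1005 list members 958 had a row in the table and 47 had none. Because genes of one list move together, camera was also run with a correlation estimated from the residuals, where 0 lists passed in each comparison (lowest adjusted p 0.50, 0.230 and 0.0667 in LPS with Control, Selfox with Control and Selfox with LPS, against 12, 17 and 20 lists past with the preset). Counts given as adjusted over the list alone use the members of that list as the family of tests.

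Genes named in the text follow a rule: the 8 largest rises and 8 largest falls of each comparison among genes past the threshold with a mean log2 CPM of at least 1, up to 4 members of each list by adjusted p (2 where none passed), and 6 genes per direction shared by both models. Members of many counts of 5 or fewer are named too, chosen after their values were seen, and those of other such counts are left unnamed. A few of the largest changes are left out of the text because their function was unsure. The groups, comparisons, gene lists, named-gene rule, split controls and alternative settings were fixed before the data were examined. The small-count rule and the runs without the late-clock libraries and with a clock covariate were added later. So were the runs at equal depth and with counts divided by 2, the shared counts with 1 control left out and the list of fasting genes. The fit without a block of the libraries with shared replicate numbers was added later too. Lists share members, such as the C1q genes of the Kupffer cell and complement lists.

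The steps were tested on simulated data built from these dispersions. Of 67 genes changed 2-fold 56 were recovered in LPS with Control, 58 in Selfox with Control and 58 in Selfox with LPS; of 67 changed 1.5-fold 41, 33 and 39 were, and of 66 changed 4-fold 66, 66 and 64. False calls made up 6.32%, 4.27% and 5.29% of all calls, and 0 of 40 random lists passed in each comparison. Genes were simulated without correlation, so the random lists do not test the list calls where genes of a list move together. Overlap between the 2 models was compared with 20 simulations of unchanged groups and with 20 fits in which the controls were split 3 and 3. In these simulations every library, controls included, was drawn around the Control means, each gene independently. Both comparisons shared the simulated controls.

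Alternatives were RLE and upper-quartile factors, no filter and a stricter one with a minimum count of 50, DESeq2, limma voom with sample weights, fits of the 2 groups alone, each library left out in turn, fry in place of camera, counts thinned to equal depth and counts divided by 2. Camera compares a list with all other genes, while fry asks whether the list's own genes shift. A list that passed with fry alone therefore need not stand out from the other genes. A block for the replicate numbers shared by LPS and Selfox was also fitted. No batch, sex, date or hour of collection is given in the labels, so none of these was modelled. Depth differed between groups: Control libraries had 31.9 to 53.8 M counts and those of the models 65.1 to 79.2 M. No library and no column was left out of the 3 comparisons.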

Results

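The series deals with rat models of portosinusoidal vascular disease, a disorder of the small vessels of the liver. RNA was sequenced from whole liver of Sprague Dawley rats as 23 libraries in 3 groups. The 6 Control libraries came from rats labelled as untreated. The 7 LPS libraries came from rats given lipopolysaccharide, a bacterial cell wall component, at 1 mg/kg through a surgically placed catheter into the portal system, 2 times per week for 8 weeks. The 10 Selfox libraries came from rats on a selenium-enriched diet for 8 weeks that also received 8 weekly intravenous injections of oxaliplatin at 3 mg/kg, 5-fluorouracil at 25 mg/kg and folinic acid at 45 mg/kg, a platinum and fluoropyrimidine chemotherapy. Total counts ranged from 31.9 to 53.8 M (mega) in Control (39.2 ± 8.30 M, SD, n = 6), from 70.4 to 79.2 M in LPS (75.6 ± 2.82 M, n = 7) and from 65.1 to 74.8 M in Selfox (71.7 ± 3.65 M, n = 10), so depth differed between Control and both models. Albumin (Alb) took 13.4 ± 1.78% of the counts in Control, 10.9 ± 2.03% in LPS and 9.42 ± 0.954% in Selfox, and the mitochondrially encoded messenger RNAs took 5.38 ± 0.548%, 5.22 ± 0.414% and 6.30 ± 0.354%. The LPS rats also had surgery and a catheter, which no label gives for Control, and Selfox rats had diet and drugs together, so these parts cannot be separated. The labels do not state that each library is a different rat; p-values measure the spread between libraries.

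The first principal component of log2 counts per M (CPM) held 21.4% of the variance, the second 12.7%. Control 55 lay apart from the other 5 Control libraries, at -5.25 on the second component against 18 to 30.91. Its Fasn, which encodes fatty acid synthase, stood at 10.60 log2 CPM against 5.77 to 7.57 in the other controls and 8.64 to 11.81 in LPS. In 5 libraries, Control 55, LPS 5, LPS 6, LPS 7 and Selfox 8, the clock output gene Dbp exceeded the core clock gene Arntl; in the other 18 it was lower. Dbp and Arntl oscillate in antiphase over the day, and these 5 are called the late-clock libraries. LPS thus held 3 of 7 late-clock libraries, Control 1 of 6 and Selfox 1 of 10. Selfox 8 joined them by a near tie, with Dbp at 3.352 and Arntl at 3.348 log2 CPM. It also had the highest Cxcl10 of all libraries (10.04 log2 CPM). A Selfox call lost without the late-clock libraries therefore cannot be ascribed to the clock.

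**Figure D1:**
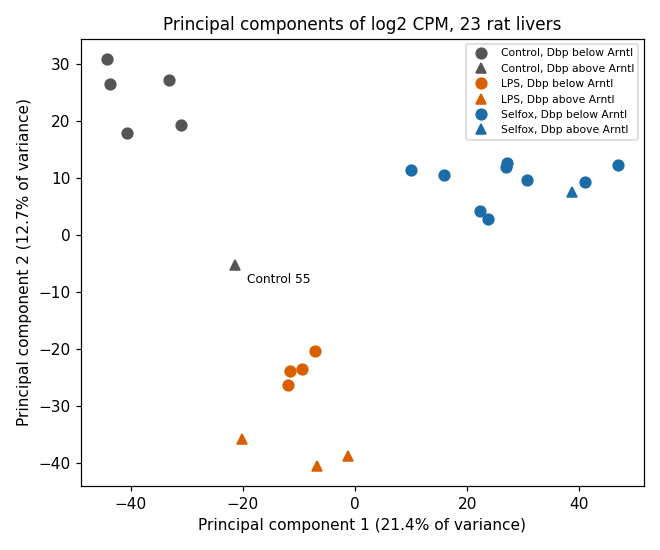
Principal components 1 and 2 of log2 CPM over the 15079 genes tested, 1 point per library, coloured by group, with triangles for the 5 libraries in which Dbp exceeded Arntl. Control 55 lies at -5.25 on the second component, below the other controls (18 to 30.91).

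The comparison of LPS with Control asks what 8 weeks of portal LPS changed in liver gene expression. Of cholesterol synthesis genes 18 of 25 rose, of lipogenesis genes 13 of 20, and of fatty acid oxidation genes 17 of 26 fell. In LPS livers 16 of 37 interferon-stimulated genes were lower, and 1 of 29 cytokine genes changed. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2217 of 15079 genes changed, 1163 higher and 1054 lower, and 453 of them by at least 2-fold (267 higher, 186 lower). The count was 1409 without Control 49 and 2723 without Control 55.

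Of the largest rises (log2 fold change ± SE), Igh-6, an immunoglobulin heavy chain gene, rose by 3.14 ± 0.55 (adjusted p = 0.000955), from 4.07 ± 4.44 to 35.6 ± 8.56 CPM (mean ± SD), and all 7 LPS libraries lay above every control. Ptprt, a receptor tyrosine phosphatase, rose by 2.97 ± 0.42 (adjusted p = 0.000174, 7 of 7 LPS libraries above every control). Pnpla3 and Pnpla5, lipid droplet lipases of the patatin family, rose by 3.56 ± 1.19 and 3.12 ± 0.84. Lcn2, an iron-binding acute phase protein, rose by 4.58 ± 1.30, and Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, by 4.17 ± 1.14. Lcn2 was highest in LPS 5, and without that library the change was 2.22 (adjusted p = 0.130, the highest of the 3 of 13 left-out fits that lost the call). The call of Pnpla3 was lost in 10 of the 13 fits that left out 1 library, while without Control 55 its rise was 6.92. Sdr16c6, a short-chain dehydrogenase, rose by 3.19 ± 1.04 from 0.0309 ± 0.0374 CPM, a call lost in 8 of the 13 fits. The calls of Lcn2, Cyp1a1 and Pnpla5 were also lost with limma voom and with the 2 groups fitted alone.

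Among the falls, Pla2g4c, a phospholipase A2, fell by 3.79 ± 0.37 (adjusted p = 5.88e-06), from 5.33 ± 1.86 to 0.384 ± 0.219 CPM, below every control in all 7 LPS libraries. The soluble epoxide hydrolase gene Ephx2 fell by 3.16 ± 0.76, the fatty acid hydroxylase gene Cyp4a2 by 2.83 ± 0.54, the drug-metabolizing Cyp2b2 by 2.65 ± 0.43, the pantetheinase gene Vnn1 by 2.54 ± 0.42 and the fatty acid binding protein gene Fabp7 by 2.51 ± 0.27. Cyp4a, Cyp2b and immunoglobulin genes have near-identical copies that can share reads, so their values are uncertain.

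In the cholesterol synthesis list 18 of 25 measured genes rose, 22 adjusted over the list alone (camera adjusted p = 4.78e-11), with Pmvk up by 1.28 ± 0.21 (7 of 7 LPS libraries above every control), Fdps by 1.28 ± 0.24, Dhcr7 by 1.19 ± 0.23 and Mvk by 1.01 ± 0.20. For lipogenesis 13 of 20 measured genes rose, 16 adjusted over the list alone (adjusted p = 5.80e-08). These included Acacb, an acetyl-CoA carboxylase, at 1.83 ± 0.35, the transcription factor Srebf1 at 1.68 ± 0.40, Acss2 at 1.59 ± 0.31 and the citrate carrier Slc25a1 at 0.62 ± 0.11. Among genes of fatty acid oxidation and other PPARa targets 17 of 26 measured genes fell, 18 adjusted over the list alone (adjusted p = 8.47e-10). Cyp4a1 fell by 2.19 ± 0.33, the thioesterase gene Acot2 by 2.02 ± 0.25 (7 of 7 below every control), the carnitine palmitoyltransferase gene Cpt2 by 1.20 ± 0.16 and Hadhb by 0.92 ± 0.13. All 3 lists had adjusted p = 0.50 with an estimated correlation. Control 55 moved with these lists: relative to the mean of the other controls its median was 0.90 for cholesterol synthesis, 1.26 for lipogenesis and -0.53 for fatty acid oxidation, against -0.44 to 0.19, -0.59 to 0.14 and -0.11 to 0.27 in each of the others. Values of the others were taken against a mean that included Control 55, which adds to the gap.

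**Figure D2:**
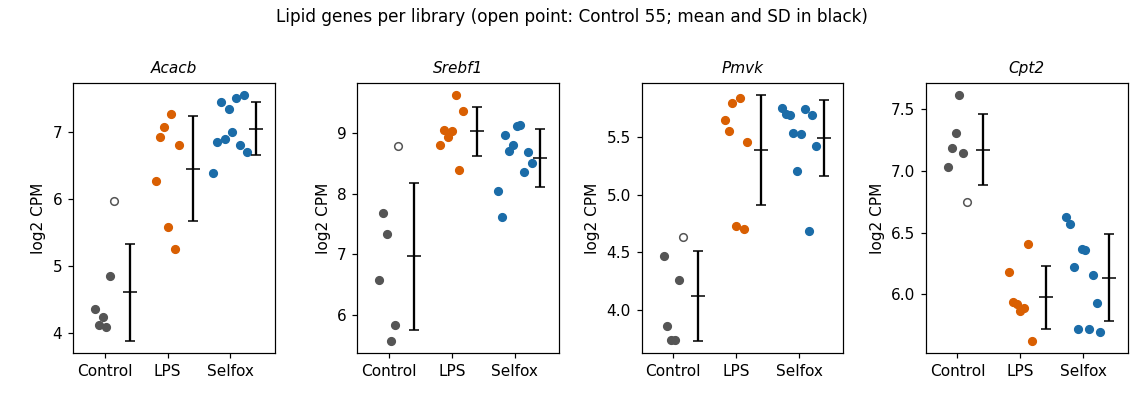
Log2 CPM of Acacb, Srebf1, Pmvk and Cpt2 per library (points, coloured by group) with the group mean and SD in black; the open point is Control 55. Acacb, Srebf1 and Pmvk were higher and Cpt2 lower in both models than in Control, and of the controls Control 55 had the highest Acacb, Srebf1 and Pmvk and the lowest Cpt2.

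Among interferon-stimulated genes 1 of 37 measured genes rose and 16 fell, 1 and 20 adjusted over the list alone (adjusted p = 2.22e-07). Oas1b fell by 1.76 ± 0.32, Mx1 by 1.60 ± 0.33, Ifit3 by 1.32 ± 0.29 and the transcription factor gene Irf9 by 0.81 ± 0.15, while the gene that rose was the proteasome subunit Psmb9 (0.44 ± 0.14, lost in 5 of 13 left-out fits). For cell cycle genes 8 of 30 measured genes fell, 19 adjusted over the list alone (adjusted p = 9.26e-07), and the cyclin gene Ccnd1 fell by 0.93 ± 0.25; without the late-clock libraries 14 fell. Of cytosolic ribosomal protein genes 17 of 35 measured genes rose, 23 adjusted over the list alone (adjusted p = 3.62e-09), for example Rps23 (0.35 ± 0.075) and Rpl19 (0.35 ± 0.078). For nuclear genes of oxidative phosphorylation 7 of 30 measured genes rose, 10 adjusted over the list alone (adjusted p = 8.32e-06), among them Ndufv2 (0.49 ± 0.10); without the late-clock libraries 13 rose. Interferon-stimulated, cell cycle and ribosomal lists had adjusted p = 0.50 with an estimated correlation, and oxidative phosphorylation 0.663 (0.0588 with fry, another list test).

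In the periportal hepatocyte list 10 of 24 measured genes rose and 1 fell, 11 and 1 adjusted over the list alone (adjusted p = 0.00110). The urea cycle genes Ass1 and Cps1 rose by 0.61 ± 0.12 and 0.59 ± 0.13, Uroc1 by 0.51 ± 0.11 and the cadherin gene Cdh1 by 0.68 ± 0.15. The gene that fell was Igf1 (-0.45 ± 0.13, lost without Control 41 or 46). Among acute phase genes 8 of 25 measured genes rose, 9 adjusted over the list alone (adjusted p = 0.00244), with ceruloplasmin (Cp) up by 0.64 ± 0.15. The list was not past the threshold without Control 55 (adjusted p = 0.0548) or without the late-clock libraries (adjusted p = 0.0595, 3 genes higher), nor with fry (0.0771). For T and NK cell markers 2 of 25 measured genes rose and 0 fell, 9 and 1 adjusted over the list alone (adjusted p = 0.00424, and 0.0924 without the late-clock libraries, where 0 rose and 1 fell), the risers being Cd2 (1.01 ± 0.28) and the granzyme gene Gzma (0.55 ± 0.17, lost in 7 of 13 left-out fits). In the list of selenium and one-carbon metabolism 5 of 27 measured genes rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p = 0.0391). Aldh1l1 rose by 0.82 ± 0.16, Sardh by 0.73 ± 0.12, Scly by 0.52 ± 0.12, Mthfd1 by 0.49 ± 0.14 and Dmgdh by 0.35 ± 0.11, the last 2 calls being lost in 3 and 5 of 13 fits. That list call was lost without Control 46, 49 or 55, LPS 1 or LPS 5 (adjusted p from 0.0531 to 0.0716) and without the late-clock libraries (0.0924). Over all genes tested 1054 of 15079 fell. In the unfolded protein response list 3 of 24 measured genes did, 3 adjusted over the list alone (adjusted p = 0.0413). They were Creld2 (-0.85 ± 0.17), Hyou1 (-0.46 ± 0.14, lost in 2 of 13 fits) and Hspa5 (-0.33 ± 0.10, lost in 3 of 13 fits). This list call too was lost without Control 46 or 55 or LPS 5 or 6 (adjusted p from 0.0714 to 0.158) and without the late-clock libraries (0.640), as it was with the stricter filter (0.0565), the clock covariate (0.0921) and fry (0.0884). With an estimated correlation, adjusted p = 0.50 for periportal, T and NK cell and one-carbon genes and 0.663 for acute phase and unfolded protein response genes.

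Members named in this and the other paragraphs because 5 or fewer moved were chosen after their values were seen. None of the 24 sinusoidal endothelial markers passed the test by edgeR (camera adjusted p = 0.0825, below the threshold without LPS 1, 2 or 4). The nearest were Lyve1 at -0.35 ± 0.12 (adjusted p = 0.0606, 5 of 7 LPS libraries below every control) and Fcgr2b at -0.35 ± 0.13 (adjusted p = 0.0677, 4 of 7). Of 19 vascular endothelial and capillarisation markers Vwf (von Willebrand factor) and Aqp1 rose, by 0.69 ± 0.11 and 0.72 ± 0.22. The call of Aqp1 was lost in 5 of 13 left-out fits. Of 22 vasoactive and shear-responsive genes 0 passed (camera adjusted p = 0.422). Of 21 stellate cell markers Tcf21 rose (0.89 ± 0.21), and of 12 smooth muscle markers Mylk (0.36 ± 0.094) and Myl9 (0.35 ± 0.11, lost in 9 of 13 fits) did. Of 20 Kupffer cell and macrophage markers Adgre1 rose (0.68 ± 0.18, list adjusted p = 0.536). Jchain, the joining chain of secreted antibodies, rose by 1.55 ± 0.32 among 12 B and plasma cell markers. The cholangiocyte and ductular markers Epcam (0.71 ± 0.14), Krt7 (1.44 ± 0.36) and Cldn4 (1.44 ± 0.37) rose out of 17. Lcn2 was the 1 riser among 11 neutrophil markers. None of 9 erythroid markers passed, Slc4a1 being nearest at 0.64 ± 0.23 (adjusted p = 0.0568, 5 of 7 above every control).

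Genes of LPS sensing gave 1 rise and 2 falls among 17. Aoah, the enzyme that removes acyl chains from LPS, rose by 1.14 ± 0.27 (adjusted p = 0.00734, 5 of 7 above every control), and the LPS receptor gene Tlr4 fell by 0.74 ± 0.22, a call lost without Control 46 or Control 52 (adjusted p up to 0.0650). Irak1 fell by 0.22 ± 0.073, a call lost in 7 of 13 fits. Among 29 cytokine and NF-kB genes the chemokine gene Cxcl14 rose (1.05 ± 0.33, lost in 7 of 13 fits), and 0 passed adjusted over the list alone. Of 17 clock genes 3 rose, among them Bhlhe40 (1.47 ± 0.26) and Per2 (1.84 ± 0.55, lost in 7 of 13 fits), and the list passed with fry alone (adjusted p = 0.00807, 0.104 by camera). Late-clock libraries were 3 of the 7 in LPS and 1 of the 6 in Control. Without them the median log2 fold change of the list was 0.097, against 0.558 with all libraries. In that fit 4 clock genes rose and 1 fell (camera adjusted p = 0.317). Of 21 immediate early genes Jund rose (0.72 ± 0.19) and Fosb fell (-1.43 ± 0.45, lost in 5 of 13 fits).

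The comparison of Selfox with Control asks what 8 weeks of the selenium diet with oxaliplatin, 5-fluorouracil and folinic acid changed. Of Kupffer cell markers 14 of 20 fell, as did 6 of 12 B and 6 of 25 T and NK cell markers. Rises took in 16 of 20 lipogenesis, 12 of 25 cholesterol synthesis and 20 of 30 oxidative phosphorylation genes. Among targets of p53 (9 of 26) and of NRF2 (11 of 29) a minority rose, and 7 of 12 contractile genes of smooth muscle did. The chemokine gene Cxcl10 reached high levels in some Selfox livers. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 4385 of 15079 genes changed, 2250 lower and the rest (48.7%) higher, 787 of them by at least 2-fold (503 higher, 284 lower).

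Of 20 Kupffer cell and macrophage markers 14 fell and 1 rose, 15 and 1 adjusted over the list alone (camera adjusted p = 1.65e-10, adjusted p = 0.230 with an estimated correlation). The scavenger receptor gene Marco fell by 2.94 ± 0.14 (adjusted p = 7.70e-13), from 84.3 ± 19.4 to 11 ± 2.43 CPM, and all 10 Selfox libraries lay below every control. The complement receptor gene Vsig4 fell by 2.03 ± 0.12 (10 of 10 below every control), the lectin gene Clec4f by 1.68 ± 0.14 and Cd5l by 1.26 ± 0.13. The riser was Cd14, the LPS co-receptor, at 0.92 ± 0.25. For B and plasma cell markers 6 of 12 measured genes fell, 6 adjusted over the list alone (adjusted p = 0.00178). Among them were Blk at -1.21 ± 0.23, Cd79b at -1.09 ± 0.32 and Cd37 at -0.67 ± 0.12. For T and NK cell markers 1 of 25 measured genes rose and 6 fell, 1 and 6 adjusted over the list alone (adjusted p = 0.0346). These included Cd4 at -1.01 ± 0.15, a gene that macrophages of the rat also express, Cd3g at -0.87 ± 0.25 and Cd8a at -0.68 ± 0.18. The riser was the chemokine gene Xcl1 (1.07 ± 0.34, lost without Control 49). For MHC class II 3 of 8 measured genes fell, 3 adjusted over the list alone (adjusted p = 0.0357): RT1-Da (-0.50 ± 0.15), RT1-Ba (-0.53 ± 0.16, lost without Control 52) and the invariant chain Cd74 (-0.57 ± 0.17, lost without Control 49 or 52). Adjusted p = 0.230 with an estimated correlation for B cells, 0.633 for T and NK cells and 0.690 for MHC class II. The T and NK call was lost without Control 41 or Selfox 3, 6 or 9 (adjusted p up to 0.0676), with the stricter filter (0.0503) and with the clock covariate (0.0517), and the MHC class II call without Control 41, 49 or 52 or Selfox 1, 2 or 6 (adjusted p up to 0.0620).

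**Figure D3:**
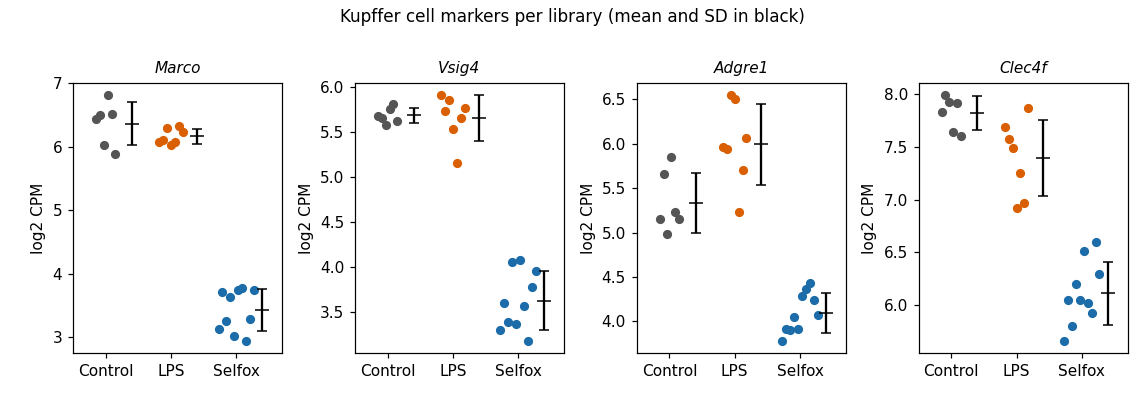
Log2 CPM of the Kupffer cell markers Marco, Vsig4, Adgre1 and Clec4f per library (points, coloured by group) with the group mean and SD in black. Marco averaged 84.3 ± 19.4 CPM in Control, 71.9 ± 5.75 in LPS and 11 ± 2.43 in Selfox (mean ± SD).

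In the other direction, of neutrophil markers 5 of 11 measured genes rose, 5 adjusted over the list alone (adjusted p = 0.0357, adjusted p = 0.692 with an estimated correlation). Mmp8 rose by 3.24 ± 0.98, S100a8 by 2.47 ± 0.79, S100a9 by 2.30 ± 0.71, Mmp9 by 2.06 ± 0.70 (lost in 5 of 16 fits without 1 library) and Csf3r by 1.27 ± 0.42. The S100a8 call was lost without Control 52 and that of Csf3r without Control 41 or 52. S100a8 lay at 2.86 to 4.77 log2 CPM in Selfox 3, 4, 5, 8 and 10. In Selfox 1, 2, 6, 7 and 9 it lay at -0.51 to 0.84, within the controls (-0.65 to 1.76). All 5 gene calls and that of the list were lost without the late-clock libraries (list adjusted p = 0.110), and the list call also without any 1 of Control 41, 52 and 55 and Selfox 3, 4, 5, 8 and 10 (adjusted p from 0.0522 to 0.0998). It was lost too at equal depth (adjusted p = 0.0529), with counts divided by 2 (0.0682), with the stricter filter (0.0811), with the clock covariate (0.0530) and with fry (0.0778). Of cytokine and NF-kB genes 18 of 29 rose and 3 fell, 20 and 3 adjusted over the list alone (adjusted p = 0.00442, adjusted p = 0.692 with an estimated correlation, 0.0879 without the late-clock libraries, 0.0563 with fry). Ccl2 rose by 6.13 ± 1.11 and Ccl4 by 3.54 ± 0.70, and Ccl6 (-0.92 ± 0.13), Cxcl12 (-0.86 ± 0.14) and Il18 (-0.37 ± 0.12, lost without Control 40 or 41) fell. Without the late-clock libraries 10 cytokine and NF-kB genes rose. The interferon-induced chemokine gene Cxcl10 rose by 5.68 ± 1.30 with a wide spread: 5.70 to 10.04 log2 CPM in Selfox 3, 4, 5, 6, 8 and 10, and 1.78 to 2.81 in Selfox 1, 2, 7 and 9. Tnfaip3, an inhibitor of NF-kB signalling, rose by 4.06 ± 0.81. It lay at 7.23 to 8.97 log2 CPM in Selfox 3, 4, 5, 8 and 10, 5.95 in Selfox 6 and 3.69 to 4.69 in Selfox 1, 2, 7 and 9. Ccl2 lay at 4.45 to 6.62 in Selfox 3, 4, 5, 8 and 10 and at -0.067 to 2.93 in the other Selfox libraries. In limma voom the calls of Ccl2 and Cxcl10 were lost.

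**Figure D4:**
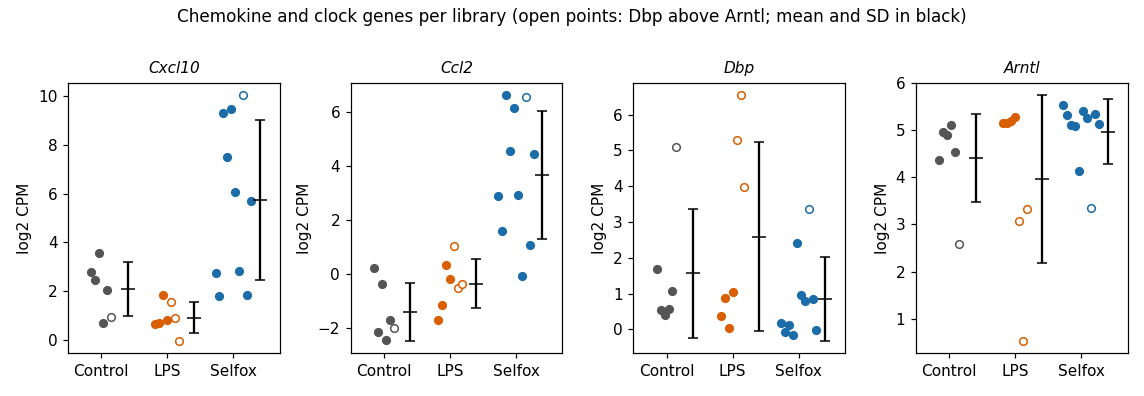
Log2 CPM of the chemokine genes Cxcl10 and Ccl2 and the clock genes Dbp and Arntl per library (points, coloured by group) with the group mean and SD in black; open points are the 5 libraries in which Dbp exceeded Arntl. Cxcl10 lies between 5.70 and 10.04 in 6 of the 10 Selfox libraries and between 1.78 and 2.81 in the other 4.

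In the lipogenesis list 16 of 20 measured genes rose and 1 fell, 16 and 1 adjusted over the list alone (adjusted p = 5.46e-08, adjusted p = 0.445 with an estimated correlation). The stearoyl-CoA desaturase gene Scd rose by 3.09 ± 0.50 (10 of 10 above every control), Acacb by 2.32 ± 0.34, Acss2 by 1.67 ± 0.30 and Slc25a1 by 0.77 ± 0.11. For cholesterol synthesis 12 of 25 measured genes rose, 13 adjusted over the list alone (adjusted p = 0.000388, adjusted p = 0.642 with an estimated correlation). Examples were Pmvk at 1.36 ± 0.20 and Fdps at 1.12 ± 0.22, and without the late-clock libraries 20 rose. For fatty acid oxidation 2 of 26 measured genes rose and 14 fell, 3 and 16 adjusted over the list alone (adjusted p = 2.14e-05, adjusted p = 0.480 with an estimated correlation). Acot2 fell by 1.75 ± 0.22, Cpt2 by 1.02 ± 0.15 and Hadhb by 0.87 ± 0.12, while Angptl4 (1.58 ± 0.48) and Cidec (0.34 ± 0.11, lost without Control 52) rose. Control 55 stood apart from the other controls in these 3 lists. Of nuclear oxidative phosphorylation genes 20 of 30 measured genes rose, 23 adjusted over the list alone (adjusted p = 2.95e-08). Members included Sdhb at 0.55 ± 0.11 and Uqcrc1 at 0.39 ± 0.073, and of mitochondrially encoded genes 6 of 13 measured genes rose, 6 adjusted over the list alone (adjusted p = 0.00178). Among them were Mt-nd5 at 0.43 ± 0.12. In the periportal list 12 of 24 measured genes rose, 12 adjusted over the list alone (adjusted p = 0.00133). These included Ass1 at 0.77 ± 0.11 and Otc at 0.63 ± 0.12. Adjusted p = 0.516 with an estimated correlation for oxidative phosphorylation, 0.632 for mitochondrially encoded and 0.480 for periportal genes.

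For p53 targets 9 of 26 measured genes rose and 1 fell, 9 and 1 adjusted over the list alone (adjusted p = 0.00178, adjusted p = 0.230 with an estimated correlation). The death receptor gene Eda2r rose by 3.65 ± 0.56 (adjusted p = 6.28e-05, 10 of 10 Selfox libraries above every control), from 0.0835 ± 0.0778 to 1.07 ± 0.368 CPM, Sesn1 by 0.82 ± 0.16, Perp by 0.59 ± 0.10 and the pro-apoptotic Bax by 0.49 ± 0.10, and Plk3 fell (-0.58 ± 0.18, lost without Control 40 or 52). NRF2 targets gave 11 rises and 1 fall among 29, 12 and 1 adjusted over the list alone (adjusted p = 0.0287, adjusted p = 0.633 with an estimated correlation). The glutathione transferase gene Gsta3, which has close paralogs, rose by 3.60 ± 0.64 and Tkt of the pentose phosphate pathway by 0.93 ± 0.18, and Trib3 fell by 1.52 ± 0.27. That list call was lost without Control 41 (adjusted p = 0.0807) or Selfox 1 (0.0614) and with the clock covariate (0.0530). In the unfolded protein response list 10 of 24 measured genes fell, 10 adjusted over the list alone (adjusted p = 0.00444, adjusted p = 0.516 with an estimated correlation). Examples were Herpud1 at -1.04 ± 0.20 and Creld2 at -0.67 ± 0.16. For immediate early genes 7 of 21 measured genes rose, 7 adjusted over the list alone (adjusted p = 0.0346, adjusted p = 0.692 with an estimated correlation). Members included Cyr61 at 2.08 ± 0.49 and Egr2 at 1.90 ± 0.38. The immediate early call was lost without the late-clock libraries (0.172, 4 genes higher) and without any 1 of Control 41, 46, 49 and 55 and Selfox 3, 5, 8 and 10 (adjusted p up to 0.107), with the stricter filter (0.0503) and with fry (0.0641).

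Of contractile genes of smooth muscle and myofibroblasts 7 of 12 measured genes rose, 7 adjusted over the list alone (adjusted p = 0.000376, adjusted p = 0.230 with an estimated correlation). Alpha smooth muscle actin (Acta2) rose by 1.29 ± 0.16 (10 of 10 above every control), from 4.18 ± 0.537 to 10.2 ± 2.56 CPM, Lmod1 by 1.19 ± 0.16 and Myl9 by 0.64 ± 0.11. Of 33 collagen and matrix genes 10 rose and 1 fell, 13 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.130, and 0.0311 without Selfox 6). Thbs1 rose by 2.17 ± 0.47, the growth factor gene Ctgf by 1.31 ± 0.26 and Col12a1 by 1.13 ± 0.22, and Mmp14 fell by 0.75 ± 0.16. Stellate cell markers went both ways, with rises of Rgs5 (0.77 ± 0.15), Fbln2 (0.73 ± 0.20), Des (0.65 ± 0.19) and Lrat (0.52 ± 0.15) and falls of Hgf (-0.59 ± 0.14), Ecm1 (-0.40 ± 0.10), Colec11 (-0.34 ± 0.083) and Pdgfra (-0.39 ± 0.13, lost without Control 41, 46 or 49) among 21. Sinusoidal endothelial markers also went both ways (list adjusted p = 0.692): of 24, Il1a (1.18 ± 0.31), Cd36 (0.88 ± 0.25), Wnt9b (0.67 ± 0.24), Bmp2 (0.46 ± 0.17) and Kdr (0.46 ± 0.16) rose and Clec1b (-0.58 ± 0.12), Oit3 (-0.42 ± 0.15) and Flt4 (-0.39 ± 0.14) fell. The calls of Wnt9b, Bmp2, Oit3, Flt4 and Kdr were lost in at least 4 of the 16 fits that left out 1 library. Other vascular genes went both ways, and their lists did not pass. Of 22 vasoactive and shear-responsive genes 4 rose and 4 fell (camera adjusted p = 0.969). Of 19 vascular endothelial markers 4 rose and 3 fell (camera adjusted p = 0.969). Among the members the vasoconstrictor gene Edn1 rose by 2.33 ± 0.54, Nos3 (endothelial nitric oxide synthase) by 0.42 ± 0.10 and Vwf by 0.56 ± 0.10. Ednra fell by 1.48 ± 0.36, Esm1 by 1.70 ± 0.36, the endothelial transcription factor gene Sox17 by 1.08 ± 0.16 and thrombomodulin (Thbd) by 0.86 ± 0.19.

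The sterol transporter genes Abcg5 and Abcg8 fell by 3.08 ± 0.50 and 2.29 ± 0.58, Phgdh, the first enzyme of serine synthesis, by 2.85 ± 0.46, Ephx2 by 2.84 ± 0.66, the acyltransferase gene Gpat3 by 2.59 ± 0.69 and histidine decarboxylase (Hdc) by 2.36 ± 0.44. Sdr16c6 rose by 7.30 ± 0.87, Pnpla5 by 4.94 ± 0.87 and Pnpla3 by 4.60 ± 1.23 (7.96 without Control 55). Thymidylate synthase (Tyms), the target of 5-fluorouracil, rose by 0.80 ± 0.11 and thymidine kinase (Tk1) by 0.68 ± 0.14 among 30 cell cycle genes, of which Ccne1 fell by 1.77 ± 0.28. The selenoprotein list passed with fry alone (adjusted p = 0.0498, 0.345 by camera): Gpx2 (1.78 ± 0.49), Selenok (0.50 ± 0.11), Selenoh (0.32 ± 0.11, lost without Control 46, 49 or 52), Selenof (0.29 ± 0.081) and Selenot (0.20 ± 0.064, lost without Control 49) rose and Dio1 (-0.55 ± 0.13), Txnrd3 (-0.38 ± 0.14, lost in 10 of 16 fits) and Selenos (-0.30 ± 0.088) fell out of 20. Unlike camera, fry does not compare a list with all other genes, and 29.1% of all genes tested changed in Selfox. The ductular markers Epcam (0.83 ± 0.14), Krt19 (0.59 ± 0.19, lost without Control 41) and Ggt1 (0.77 ± 0.28, lost in 9 of 16 fits) rose. Their list had adjusted p = 0.0766, and 0.00395 with fry, 0.0413 without Control 40 and 0.0498 without Control 52. Of 9 erythroid markers Slc4a1 rose (0.73 ± 0.21) and Itga2b fell (-0.48 ± 0.13). Genes of the clock went both ways, among them rises of Bhlhe40 (1.13 ± 0.24) and Cry1 (1.0 ± 0.30) and falls of Per1 (-0.65 ± 0.20), Nr1d1 (-1.72 ± 0.54), Nr1d2 (-0.93 ± 0.34) and Tef (-0.77 ± 0.28). With 1 library left out the Tef call was lost in 14 of 16 fits, that of Nr1d2 in 13 and that of Nr1d1 in 1.

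The comparison of Selfox with LPS asks where the models differed from each other. Lower in Selfox were 14 of 20 Kupffer cell, 15 of 25 T and NK cell, 5 of 12 B cell and 6 of 8 MHC class II genes. Higher were 20 of 30 cell cycle and 6 of 12 contractile genes, and a minority of NRF2 (10 of 29), p53 (8 of 26) and interferon-stimulated genes (10 of 37). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 2187 of 15079 genes differed, 1035 higher and 1152 lower in Selfox, 610 by at least 2-fold (352 higher, 258 lower). Without the 5 late-clock libraries, 3 of them LPS, the count was 1434.

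Of Kupffer cell markers 14 of 20 were lower and 1 higher, 15 and 1 adjusted over the list alone (adjusted p = 1.02e-14, adjusted p = 0.0667 with an estimated correlation). Marco differed by -2.71 ± 0.13 (10 of 10 Selfox libraries below every LPS library), Vsig4 by -2.02 ± 0.12, the macrophage gene Adgre1 by -1.95 ± 0.16 and Cd5l by -1.23 ± 0.12, and the exception was Cd14 (0.93 ± 0.24). For T and NK cell markers 15 of 25 were lower and 2 higher, 20 and 2 adjusted over the list alone (adjusted p = 1.66e-09, adjusted p = 0.0851 with an estimated correlation). Cd4 differed by -1.06 ± 0.14, the T cell receptor gene Trbc2 by -1.04 ± 0.17 and Gzma by -0.80 ± 0.15, against Klrk1 (0.80 ± 0.21) and Xcl1 (1.04 ± 0.31, lost without LPS 2). MHC class II genes were lower, 6 of 8 and 6 adjusted over the list alone (adjusted p = 4.56e-06, adjusted p = 0.198 with an estimated correlation), such as RT1-Ba (-1.11 ± 0.16) and Cd74 (-0.99 ± 0.16). B and plasma cell markers gave 5 of 12 lower, 6 adjusted over the list alone (adjusted p = 0.000779, adjusted p = 0.135 with an estimated correlation): Jchain (-1.30 ± 0.27), Blk (-0.89 ± 0.22), Mzb1 (-0.78 ± 0.26), Cd37 (-0.65 ± 0.12) and Cd22 (-0.60 ± 0.17). The Mzb1 call was lost in 13 of 17 left-out fits (adjusted p up to 0.138) and that of Cd22 in 2. Igh-6 differed by -2.51 ± 0.44. Complement genes gave 7 lower and 1 higher of 25, 7 and 1 adjusted over the list alone (adjusted p = 1.80e-06, adjusted p = 0.198 with an estimated correlation). Among them were Cfd at -1.49 ± 0.14 and the macrophage products (also Kupffer list members) C1qa, C1qb and C1qc at -0.79 ± 0.12, -0.90 ± 0.12 and -0.90 ± 0.11, and the exception was the receptor gene C3ar1 (0.72 ± 0.19).

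Cell cycle genes were higher in Selfox than in LPS: 20 of 30, 25 higher and 1 lower adjusted over the list alone (adjusted p = 3.31e-12, adjusted p = 0.198 with an estimated correlation), with Ccne1 lower (-0.99 ± 0.27). Mki67, the proliferation marker, differed by 1.51 ± 0.30 (8 of 10 above every LPS library), Aurkb by 1.51 ± 0.31, Kif11 by 0.81 ± 0.14 and Tyms by 0.74 ± 0.10. Against Control 2 of 30 cell cycle genes rose and 1 fell in Selfox (camera adjusted p = 0.248). In LPS 8 of 30 fell against Control (camera adjusted p = 9.26e-07). For NRF2 targets 10 of 29 were higher and 1, Trib3 (-0.99 ± 0.26), lower, 13 and 2 adjusted over the list alone (adjusted p = 0.000779, adjusted p = 0.263 with an estimated correlation). Gsta3 differed by 3.46 ± 0.59, the aldo-keto reductase genes Akr1b8 and Akr7a3 by 2.91 ± 0.37 and 1.85 ± 0.41 and malic enzyme (Me1) by 1.54 ± 0.32. For p53 targets 8 of 26 were higher and 1, Aen (-0.48 ± 0.13, lost without LPS 1), lower, 10 and 2 adjusted over the list alone (adjusted p = 0.00232, adjusted p = 0.198 with an estimated correlation), including Eda2r (2.67 ± 0.44) and Zmat3 (0.85 ± 0.16). Smooth muscle genes gave 6 of 12 higher, 6 adjusted over the list alone (adjusted p = 2.35e-05, adjusted p = 0.106 with an estimated correlation). These included Acta2 at 1.11 ± 0.15 and Lmod1 at 0.69 ± 0.14. Of mitochondrially encoded genes 7 of 13 were higher, 11 adjusted over the list alone (adjusted p = 4.32e-07, adjusted p = 0.198 with an estimated correlation), such as Mt-cyb (0.49 ± 0.074). Of interferon-stimulated genes 10 of 37 were higher, 12 adjusted over the list alone (adjusted p = 2.63e-06, adjusted p = 0.460 with an estimated correlation), led by Cxcl10 (7.07 ± 1.30) and the guanylate-binding protein gene Gbp5 (2.69 ± 0.47). Against Control 5 of 37 interferon-stimulated genes rose in Selfox and 8 fell (adjusted p = 0.309, and 0.0478 without Selfox 6). Without the late-clock libraries 3 interferon-stimulated genes, 3 p53 targets, 5 NRF2 targets and 4 mitochondrially encoded genes were higher in Selfox than in LPS, and these lists still passed (adjusted p up to 0.0180).

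Of ribosomal protein genes 7 of 35 were lower in Selfox, 19 adjusted over the list alone (adjusted p = 1.92e-07, adjusted p = 0.472 with an estimated correlation), for example Rpl13a (-0.27 ± 0.076). Coagulation genes gave 7 lower of 31 and 1 higher, 7 and 1 adjusted over the list alone (adjusted p = 0.00148, adjusted p = 0.198 with an estimated correlation). These included the kininogen gene Kng1 at -1.43 ± 0.25, Thbd at -1.02 ± 0.18 and Serpind1 at -0.46 ± 0.08; without the late-clock libraries 4 were lower. Of the largest differences, the chemokine genes Ccl2 (5.20 ± 0.94), Cxcl2 (4.43 ± 0.80), Ccl4 (3.68 ± 0.65) and Ccl3 (3.58 ± 0.64), the chemokine receptor-like Ccrl2 (3.46 ± 0.51), the kinase gene Ripk2 (3.62 ± 0.84) and Sdr16c6 (4.10 ± 0.56) were higher in Selfox. Abcg8 (-2.28 ± 0.56), Abcg5 (-2.09 ± 0.47), Dbp (-3.10 ± 0.95, lost in 5 of 17 fits without 1 library) and Per3 (-2.52 ± 0.80, lost in 11) were lower. Without the late-clock libraries Dbp and Per3 turned to 0.19 and 0.43, neither past the threshold, and the calls of Abcg5, Abcg8, Ripk2, Cd14 and Ccne1 were lost.

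The remaining list calls of Selfox against LPS did not hold without the late-clock libraries, where 6 cytokine, 0 neutrophil and 3 collagen genes were higher and 2 cholesterol and 2 bile acid genes lower. Cytokine and NF-kB genes gave 15 higher and 4 lower of 29, 19 and 5 adjusted over the list alone (adjusted p = 0.00149, 0.0539 without those libraries, adjusted p = 0.640 with an estimated correlation), the lower ones being Ccl6 (-0.88 ± 0.12), Ccl5 (-0.60 ± 0.13), Cxcl12 (-0.45 ± 0.13, lost without LPS 5) and Il18 (-0.37 ± 0.11, lost without LPS 2, 3 or 7). Neutrophil markers gave 6 of 11 higher, 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00925, then 0.295, adjusted p = 0.640 with an estimated correlation), such as Mmp8 (3.19 ± 0.88). Of sinusoidal endothelial markers Il1a (1.69 ± 0.29), Bmp2 (0.83 ± 0.16), Kdr (0.69 ± 0.15) and Lyve1 (0.50 ± 0.11) were higher among 24, 5 adjusted over the list alone (adjusted p = 0.00747, then 0.959, adjusted p = 0.640 with an estimated correlation). Cholesterol synthesis genes gave 6 of 25 lower, 7 adjusted over the list alone (adjusted p = 0.00747, then 0.943, adjusted p = 0.699 with an estimated correlation). Of oxidative phosphorylation genes Sdha (0.31 ± 0.063) and Ndufv1 (0.20 ± 0.056) were higher among 30, 2 adjusted over the list alone (adjusted p = 0.0158, then 0.468, adjusted p = 0.721 with an estimated correlation). Collagen and matrix genes gave 8 higher and 1, Timp2 (-0.55 ± 0.11), lower of 33, 10 and 1 adjusted over the list alone (adjusted p = 0.0158, then 0.434, adjusted p = 0.699 with an estimated correlation). Examples were Loxl2 at 1.07 ± 0.14 and the basement membrane genes Col4a1 and Col4a2 at 0.75 ± 0.16 and 0.81 ± 0.14. Bile acid genes gave 5 of 22 lower, 7 adjusted over the list alone (adjusted p = 0.0188, then 0.0579, adjusted p = 0.207 with an estimated correlation): Nr0b2 (-1.91 ± 0.29), Cyp8b1 (-0.95 ± 0.30), Fgfr4 (-0.24 ± 0.079), Abcg5 and Abcg8. The calls of Cyp8b1 and Fgfr4 were lost in 11 and 11 of 17 left-out fits. Several of these list calls were also lost with 1 library left out: sinusoidal endothelial without LPS 5 (0.0782) or LPS 6 (0.0801), cholesterol without LPS 5 (0.114), collagen without LPS 6 (0.121) or Selfox 8 (0.0547), and oxidative phosphorylation without LPS 5, LPS 7, Selfox 3 or Selfox 6 (adjusted p up to 0.138). With fry 6 of these lists did not pass: cytokine (adjusted p = 0.123), neutrophil (0.127), sinusoidal endothelial (0.120), cholesterol (0.222), oxidative phosphorylation (0.322) and collagen (0.207). The last 4 did not pass with the clock covariate either (adjusted p from 0.0816 to 0.485), nor did neutrophil markers with the stricter filter (0.0850). Over the 14 libraries with shared replicate numbers the collagen call was lost with the block (camera adjusted p = 0.153) and without it (0.212). So was the bile acid call (0.0665 and 0.0761), and the cholesterol call was lost without the block alone (0.0528).

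The check lists that did not pass in Selfox against LPS were the clock genes (adjusted p = 0.166, 7 of 17 lower, 8 lower and 1 higher adjusted over the list alone). Members included Ciart at -3.06 ± 0.82, Tef at -1.04 ± 0.27 and Per1 at -0.65 ± 0.19, with the calls of Ciart and Per1 lost without LPS 6. In the fit with a replicate block the clock list passed (adjusted p = 0.0443). The immediate early list did not pass either (adjusted p = 0.150, but 0.0265 without Selfox 2 and 0.0479 without Selfox 7). Among them were Egr3 (2.0 ± 0.42), Egr2 (1.36 ± 0.33), Fosb (1.43 ± 0.41) and Myc (0.75 ± 0.21) higher of 21. Without the late-clock libraries Ciart turned to 0.68, and 0 clock genes changed, against 7 in the fit of all libraries. Of stellate cell markers Tcf21 (-1.0 ± 0.18), Hgf (-0.58 ± 0.14), Pdgfra (-0.57 ± 0.12), Colec11 (-0.38 ± 0.079) and Ecm1 (-0.34 ± 0.095, lost without LPS 7) were lower and Thy1 (1.64 ± 0.35) and Rgs5 (0.45 ± 0.14, lost without LPS 1, 2 or 3) higher among 21. Their list had adjusted p = 0.0956, but 0.0416 with the clock covariate, 0.0474 without LPS 6, 0.0343 without Selfox 9 and 0.0286 with a replicate block (0.0373 for the same 14 libraries without it). Among vascular endothelial markers Esm1 (-2.07 ± 0.34), Sox17 (-0.68 ± 0.16) and Gja4 (-0.53 ± 0.13) were lower and Sele (5.07 ± 1.23), Apln (1.43 ± 0.32) and Fabp4 (1.12 ± 0.30) higher of 19. No cholangiocyte marker (of 17) and no erythroid marker (of 9) differed by edgeR; the nearest were Cldn4 at -0.82 ± 0.29 (adjusted p = 0.0621, 4 of 10 Selfox libraries below every LPS library) and Ahsp at 1.17 ± 0.52 (adjusted p = 0.135, 3 of 10 above).

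**Figure D5:**
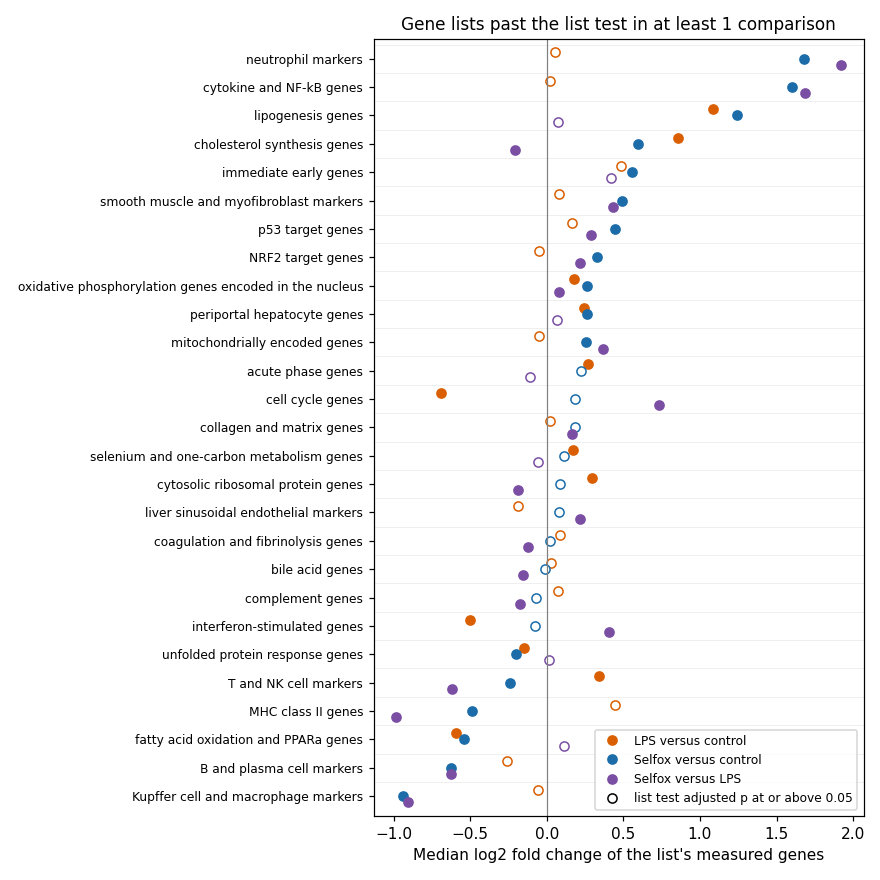
Median log2 fold change of the measured genes of each list that passed the list test in at least 1 comparison, with 1 colour per comparison and filled points where adjusted p was under 0.05. Kupffer cell markers lie at -0.94 in Selfox versus control and -0.90 in Selfox versus LPS, and lipogenesis at 1.08 and 1.24 in LPS and Selfox versus control.

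Genes changed in the same direction in both models against Control numbered 1443, 759 higher and 684 lower, and 14 changed in opposite directions. Sdr16c6, Pnpla5 and Pnpla3 rose in both (values above), as did Ptprt, by 2.97 ± 0.42 in LPS and 2.75 ± 0.40 in Selfox, and the myelin basic protein gene Mbp, by 2.13 ± 0.40 and 2.28 ± 0.39. Ephx2, Pla2g4c, Fabp7 and Vnn1 fell in both, and so did the fatty acid oxidation enzymes Ech1, by 2.04 ± 0.26 and 2.10 ± 0.23, and Eci1, by 1.91 ± 0.34 and 2.04 ± 0.30. Both comparisons use the same 6 controls, all of lower depth than every library of the models. The labels do not say whether the controls were prepared or sequenced apart. A difference of that kind would move genes alike in both models. Neither equal depth nor splitting the controls could remove it. Independent lists of these sizes would share 164.7 higher and 157.3 lower genes. The 20 simulations of unchanged groups, with simulated controls, shared 0. With no gene changed in them few can be called, so this 0 is no benchmark for 1443. With the controls split 3 and 3, so that each comparison had its own 3, the shared count was 423 (median of 20 fits, 224 to 569). The log2 fold changes correlated across genes at r = 0.555, against 0.614 in the simulations and 0.360 with split controls; genes are not independent replicates. Their covariance was 0.153 against a simulated 0.0405, a difference of 0.112. With split controls the covariance was 0.124 (median of 20 fits, 0.110 to 0.135). With 1 control left out, a test chosen after the data were seen, the shared count ran from 929 without Control 49 to 1885 without Control 55.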

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

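Every test in this part was chosen only after the result was seen, except that of the depth of Control 55. A library is listed below where its gap to the nearest other library of its group, divided by the range of the group, exceeded the 95% critical value of Dixon; chance marks about 1 in 20 groups, and 44 values in 738 groups were marked. Values are log2 CPM against the nearest other library of the group, except for a principal component. In Control 46 these were Mt-nd5 (11.22 against 10.50) and Ripk2 (3.29 against 2.98). In Control 49 it was Aen (4.55 against 5.17). In Control 52 these were Irak1 (6.80 against 6.58), Jchain (1.0 against 2.21) and Thy1 (-3.53 against -2.25). In Control 55 these were Acss2 (6.32 against 4.81), Arntl (2.6 against 4.37), Col4a1 (5.17 against 5.73), Col4a2 (4.44 against 4.90), Cyp4a1 (7.07 against 8.93), Cyp4a2 (9.22 against 11.22), Dbp (5.10 against 1.69), Eci1 (6.08 against 8.03), Ephx2 (2.31 against 6.65), Fasn (10.60 against 7.57), Fdps (8.40 against 7.29), Mmp14 (5.51 against 6.20), Mvk (3.20 against 2.67), Per2 (3.67 against 1.76), Sesn1 (5.24 against 4.72), Slc25a1 (6.77 against 6.33), Tef (5.70 against 5.10), Tkt (7.85 against 7.08) and principal component 2 (-5.25 against 18). In LPS 5 it was Cdh1 (7.41 against 6.99). In LPS 6 these were Fbln2 (-0.57 against 0.54), Mmp14 (4.61 against 5.49) and Por (9.14 against 8.45). In LPS 7 it was Cd37 (1.71 against 1.44). In Selfox 2 it was Cd3g (-2.84 against -1.75). In Selfox 4 it was Phgdh (2.32 against 0.98). In Selfox 5 it was Myl9 (2.96 against 3.33). In Selfox 6 these were Bax (4.0 against 3.69), Col12a1 (2.37 against 3.15), Dio1 (6.07 against 6.61), RT1-Ba (4.33 against 5.01), RT1-Da (4.91 against 5.47) and Txnrd3 (1.89 against 2.29). In Selfox 7 it was Kif11 (2.57 against 2.18). In Selfox 8 these were Dhcr7 (5.52 against 6.11), Pmvk (4.69 against 5.20) and Upb1 (8.25 against 8.50). In Selfox 9 it was Akr1d1 (10.85 against 10.23).

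Random regrouping of the libraries was run 100 times per comparison, the real grouping included. Only 1 of 100 groupings, the real one, called as many genes as the real one in each comparison: 2217 against at most 470 in LPS with Control, 4385 against at most 273 in Selfox with Control, and 2187 against at most 749 in Selfox with LPS. Chance assignment of libraries to groups is thus an unlikely source of these counts, though 100 groupings cannot show a share below 1 in 100. A difference in handling that follows the groups was not tested.

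Kupffer cell markers were lower in Selfox livers (median log2 fold change -0.94 against Control). Lower depth of the controls is argued against, since 14 of the 14 members called lower stayed so at equal depth. A lower share of all non-hepatocyte RNA is argued against too, as far as sinusoidal endothelial markers stand for it. They had a median of 0.080 (median absolute deviation 0.346, 24 genes), while the Kupffer markers had -0.94 (median absolute deviation 0.517). A lower share of leukocyte RNA in general was not tested. Of B cell markers 6 of 12 fell and of T and NK cell markers 6 of 25 (1 rose), while 5 of 11 neutrophil markers rose. The diet with chemotherapy remains a candidate explanation, through fewer Kupffer cells or less expression per cell, and whole-liver RNA cannot tell these apart.

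Lipid synthesis genes were higher and fatty acid oxidation genes lower in both models. Removing the late-clock libraries kept 6 of 6 list calls (camera, preset correlation), so these calls did not need the late-clock LPS and Selfox libraries. That run also removed Control 55, which moved with the models in these lists, and its removal widens the contrast. The run therefore cannot exclude a part played by clock phase. Lower depth of the controls is argued against, since 6 of 6 list calls stayed at equal depth. Livers taken in a more fed state could give the same pattern: 7 fasting response genes had medians of -0.27 in LPS (median absolute deviation 0.0686) and -0.0014 in Selfox (median absolute deviation 0.0486), which leaves this open. Among them G6pc, the last enzyme of glucose release, was higher in both, by 0.63 (adjusted p = 0.0469) and 0.73 (adjusted p = 0.00774). Control 55, an untreated liver, shows the same pattern, so the 2 treatments may not be its only source.

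Control 55 lay apart from the other controls and carried 19 of the 44 marked values. An LPS rat under a control label is argued against: on 416 genes that set LPS apart it lay at 0.397 between the other controls (0, up to 0.273) and LPS (1, lowest 0.706, SD 0.135). A Selfox rat is argued against likewise, at 0.205 on 1170 genes (other controls up to 0.157, lowest Selfox 0.660, SD 0.179), and so is depth, 44.3 M within the 31.9 to 53.8 M of the others. A late clock phase at collection may contribute. The deviation of Control 55 correlated with that of LPS 6 at 0.234, LPS 7 at 0.198 and LPS 5 at 0.107. With Selfox 8, whose Dbp and Arntl nearly tied, the correlation was -0.097. With the other libraries of the models it was at most 0.0985. These values cannot tell. The labels give no cause, beyond the clock phase no biological explanation was tested, and feeding or hour of collection is a candidate explanation.

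Tests of Control 55 were revised after their first results. The first form placed it on the 1883 genes changed in both models in a fit without it, where it lay at 0.674 (other controls -0.050 to 0.216), below every library of the models, and this was first read as arguing against a treated rat. Those libraries had helped to choose the genes; with each held out the lowest lay at 0.786 and the form decided nothing, so the 2 model-specific tests replaced it. The first clock test used Selfox 8 alone and argued against a clock phase; it was widened because LPS 5, LPS 6 and LPS 7 are late-clock libraries too.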

How the results depend on the processing

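The tests without the late-clock libraries, with the clock covariate and at equal depth were chosen only after the result was seen. Without the 5 late-clock libraries 1434 genes changed in Selfox with LPS, with fewer libraries in the fit. A replicate block over the 14 libraries with shared numbers gave 1259, against 1617 for the same 14 without it; the numbers gave no sign of pairing, as correlations of the 7 pairs ran from -0.059 to 0.160 and 1 LPS library matched its own number best. With an estimated correlation between genes 0 lists passed in LPS with Control, 0 in Selfox with Control and 0 in Selfox with LPS. Controls split 3 and 3 gave 423 genes shared by both models, with fewer controls per comparison. Leaving out 1 library gave 1409 (without Control 49) to 2723 (without Control 55) genes in LPS with Control, 3638 to 4705 in Selfox with Control and at least 1830 in Selfox with LPS, and 9 to 15, 12 to 20 and 17 to 21 lists. Genes shared by both models numbered 929 without Control 49 and 1885 without Control 55. In Selfox with LPS, 3 clock genes changed sign without the late-clock libraries and with the clock covariate, none past the threshold: Dbp to 0.19 and 0.061, Per3 to 0.43 and 0.30, Ciart to 0.68 and 0.24. The sinusoidal endothelial list call ended without those libraries (adjusted p = 0.959, 3 genes higher and 3 lower). Lists that passed only in some settings included, in LPS with Control, MHC class II without Control 49 (adjusted p = 0.0379) or 52 (0.0364). In Selfox with Control they included acute phase (0.0413) and ribosomal genes (0.0191) without Control 40, selenium and one-carbon genes with fry (0.00395) and complement genes with fry (0.0413) and without Selfox 4 (0.0430) or 6 (0.0478). In Selfox with LPS they included acute phase genes without LPS 6 (0.0419) or Selfox 4 (0.0182), fatty acid oxidation genes without LPS 1 (0.0245), LPS 4 (0.0454) or Selfox 10 (0.0284) and over the 14 libraries with (0.0104) and without the block (0.0171), and unfolded protein response genes without the late-clock libraries (0.0204) and with the clock covariate (0.0416). For each of these shifts the cause was not tested. DESeq2 gave 2680, 4754 and 2649 genes and limma voom 3141, 5109 and 2502. Of 515 named gene calls 122 were lost in at least 1 fit that left out 1 library, 117 in at least 1 other setting fixed in advance and 113 without the late-clock libraries. Control libraries had the lowest depth; thinned to equal depth, 2037, 4147 and 1872 genes changed.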

Other observations

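In Selfox livers 6 further gene lists did not pass camera, 2 of them passed with fry, and their members changed in both directions; of all genes tested 29.1% changed. Of 29 hypoxia and angiogenesis genes 4 rose and 3 fell (adjusted p = 0.853): the growth factor gene Pdgfb rose by 2.07 ± 0.34 and the oxygen sensor gene Egln3 by 2.98 ± 0.67, and the Notch target Hey1 fell by 1.92 ± 0.30. Of 28 xenobiotic cytochrome P450 genes 4 rose and 4 fell (adjusted p = 0.969), among them Por, the electron donor of these enzymes, down at -0.81 ± 0.15 against Control, and Cyp2c22 up at 0.87 ± 0.21. Pericentral hepatocyte genes gave 1 rise and 6 falls of 21 (adjusted p = 0.660), with Lect2 at -0.74 ± 0.13 and Lhpp at 0.48 ± 0.084. Of 20 fluoropyrimidine and folate genes 4 rose and 3 fell (adjusted p = 0.114, and 0.000724 with fry), with Ppat, the first enzyme of purine synthesis, at -0.80 ± 0.087 and Upb1, an enzyme of pyrimidine breakdown, at 0.72 ± 0.10. DNA repair genes gave 2 rises and 3 falls of 25 (adjusted p = 0.969), with the damage recognition gene Xpc at 0.55 ± 0.12, and platinum handling genes 4 and 2 of 13 (adjusted p = 0.660, and 0.0368 with fry).

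In LPS livers 3 further gene lists did not pass camera. Coagulation genes gave 3 rises of 31 (adjusted p = 0.0585): Kng1 (1.63 ± 0.30), Vwf (0.69 ± 0.11) and the factor IX gene F9 (0.30 ± 0.079). That list passed with fry (adjusted p = 0.0278), at equal depth (0.0431), with the clock covariate (0.0445) and without Control 40, Control 52, LPS 4 or LPS 6 (adjusted p from 0.0134 to 0.0385). Complement genes gave 4 rises of 25 (adjusted p = 0.0825, but 0.0494 without Control 52 and 0.0284 without LPS 6), among them Cfi (0.31 ± 0.078), C3 (0.32 ± 0.093, lost without Control 49 or LPS 7) and C9 (0.41 ± 0.13, lost in 8 of 13 fits without 1 library). Bile acid genes gave 4 rises of 22 (adjusted p = 0.479): Cyp7b1 (1.12 ± 0.21), Akr1d1 (0.93 ± 0.23), Cyp27a1 (0.41 ± 0.10) and the bile acid receptor gene Nr1h4 (0.40 ± 0.12, lost in 5 of 13 fits).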
